A study of Homo sapiens with 6 samples.

How the data were processed

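Polyadenylated RNA was sequenced from HT1080 cells, an established human fibrosarcoma line, in 6 libraries: 3 labelled wild type (WT) and 3 labelled PGK1 knockout (KO). The series text states that PGK1 was disrupted with CRISPR-Cas9. The guide sequence and the edited position are not given in the sources used here. All 6 libraries carry the same batch label. The labels do not say whether the 3 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these libraries, which may be technical.

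The authors deposited a table of read counts per gene and a table of FPKM values, each with 20610 gene symbols. The submitters' processing notes name fastp, HISAT and the genome build hg38, without versions. The counting tool, the annotation, the strand setting and any filter are not given in the sources used here, so genes that overlap or have near-identical copies are uncertain. The count columns hold whole numbers with a different total in each library. The authors' FPKM values equal the deposited count divided by the library total and by a fixed length per gene for all 17521 genes with a read, within a relative tolerance of 1e-06, so the FPKM table adds no independent measurement. No reads were counted in any library for 3089 genes. Of the symbols, 19458 were found as current symbols in the reference gene table, 728 as older symbols and 424 not at all.

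The summed counts were 41327783, 47047186 and 39150295 in the WT libraries and 43890830, 33262329 and 30175903 in the KO libraries. Before the scaling factors below, a count of 1 corresponded to 0.0213 to 0.0331 in scaled counts (CPM). Intervals on ratios of counts are exact 95% intervals and cover counting error only, since the reads carry no molecular identifiers.

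A gap affects the measured genes. Of 525 protein-coding genes annotated to chromosome 20, 265 had no count in any library, and these genes together held 0.0082% of all counts. Genes expressed in all dividing cells, PCNA among them, were at 0 in all 6 libraries. Values of genes on this chromosome were therefore not read as expression. The fixed gene lists lost 16 members in this way.

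Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr with its defaults, robust dispersion, group as the only term), with Benjamini-Hochberg adjustment over the 13249 genes that passed the filter and a threshold of 0.05. TMM factors were 0.921 to 0.929 in WT and 1.053 to 1.097 in KO. CPM values are taken relative to the library totals times these factors, and group values are mean ± SD over 3 libraries. The common biological coefficient of variation, estimated over all genes together, was 0.0825. Data for KO against WT were simulated from the real means and library sizes, with the same common dispersion for every gene. Changed genes were drawn only from genes above a minimum mean count, so recovery at low counts was not simulated. The test recovered 38% of 50 genes with a true log2 change of 0.32 and 88% of 50 changed 1.5-fold. It recovered 100% of 50 changed 2-fold or of 50 changed 4-fold, with 6 false calls among 13019 unchanged genes. Only 200 genes were changed, equally often up and down, whereas 76.4% of tested genes changed in the real data. The simulation therefore does not give the rate of false calls where most genes change and the scaling is less certain.

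The groups, the tests, the rule for named genes, the 30 gene lists and the other analyses listed below were fixed before the data were examined. The comparison of the G2/M list with the G1/S list was not among the fixed tests. The rule named PGK1, SLC7A11, SLC3A2, GPX4 and ACSL4 whatever their values. It also named the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and with all KO libraries on the same side of all WT libraries. For each list it named up to 4 members with the smallest p-values. Of 683 list members, 669 were found among the symbols. The 13 mitochondrially encoded genes were not among them, so that list was not tested, which left 29 lists. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, beside camera with an estimated correlation and fry, adjusted over the lists. PGK1 was left out of the list tests.

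The alternatives were other normalizations (RLE, upper quartile, library size alone), no filter or a filter of at least 1 CPM in 3 libraries, a replicate block, dispersion without the robust option, each library left out in turn, DESeq2 1.42.0, limma voom, and limma on log2(FPKM + 1) or log2(FPKM + 0.1). Other thresholds were also tried, and the list tests were repeated with genes in more than 1 list left out. After the data were seen, a fit without the genes of chromosome 20 and a removal of the trend on GC content and length were added. After that removal the lists were tested with camera on log2 CPM rather than on the counts. The lists were not tested on log2 CPM before it, so a lost call can come from either change. GC content came from the GENCODE transcripts of the reference, and length was derived from the authors' counts and FPKM values. Both were available for 13091 tested genes (98.8%). Gene positions are those of the GRCh38 reference annotation, since the deposited tables give symbols only. Figures were drawn with matplotlib 3.10.9, and other steps used NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3 under Python 3.11.15.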

Results

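The transcriptome of HT1080 fibrosarcoma cells was compared between 3 WT and 3 PGK1 KO libraries. PGK1 encodes phosphoglycerate kinase 1, which makes ATP in the lower part of glycolysis. The series links this enzyme to ferroptosis, an iron-dependent death by lipid peroxidation, and to the cystine transporter subunit SLC7A11. Library totals ranged from 30175903 to 47047186 counts. Between libraries of the same group, Pearson correlations of log2 CPM were 0.988 to 0.994, and between groups they were 0.908 to 0.912. Every pair of libraries within a group differed by more than sampling noise (chi-square per degree of freedom at least 3.75), so no library was a copy of another. KO library 3 stood furthest from its group, with a ratio of 22.4 against KO library 2.

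The targeted gene was lower in each KO library. PGK1, at positions 78104248 to 78129295 of chromosome X in GRCh38, had 55085, 62272 and 51171 counts in the WT libraries and 7144, 5515 and 5234 in the KO libraries. Its level was 1427 ± 19.9 CPM in WT and 155 ± 8.52 CPM in KO (SD, n = 3 each). The KO level was 10.9% of WT, a log2 fold change of -3.20 (SE 0.061, adjusted p = 5.13e-15, edgeR quasi-likelihood test). The testis-expressed paralog PGK2 had 0 counts in all 6 libraries. The labels of all 6 libraries therefore matched the direction of PGK1, although read counts do not show whether the remaining transcripts encode protein. Most other glycolysis genes fell as well, as given below, so the fall of PGK1 by itself does not show the edit.

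The KO cells differed from WT in most of the genes measured. Genes of the mevalonate pathway, the hypoxia response, the extracellular matrix, mitosis and glycolysis were lower in KO, whereas SLC7A11, ferritin heavy chain and genes of ribosome assembly were higher. With an estimated correlation the lists for mitosis, glycolysis and ribosome assembly were not called (adjusted p = 0.0583, 0.203 and 0.0811). Of 13249 genes tested, 10116 (76.4%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 5301 higher and 4815 lower in KO. With an absolute log2 fold change of at least 1 as a further condition, 4104 changed, 2048 higher and 2056 lower. The 2 groups did not overlap for 79.2% of tested genes, where chance gives 10%. The split by direction rests on the scaling: 52.4% of the changed genes were higher in KO with TMM, and 63.6% with library size alone, which moves the median of all genes by 0.22 on the log2 scale. The labels do not say whether the KO cells are a clone, and the identity of the KO cells as HT1080 was not checked against genotypes, so the loss of PGK1 is not separated here from other differences between clones, cultures or cell lines.

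The largest rises were in genes nearly silent in WT. MMP3, a secreted matrix protease, rose from 1.96 ± 0.35 to 674 ± 49.6 CPM (SD, n = 3 each), a log2 fold change of 8.41 (SE 0.105). MMP1, the interstitial collagenase next to it on chromosome 11, rose from 4.44 ± 0.182 to 247 ± 38.9 CPM. NOXO1, an organizer of NADPH oxidase, rose from 0.211 to 44.0 CPM. IL1RL1, the interleukin 33 receptor, and OLAH, a thioesterase of fatty acid synthesis, reached 16.3 and 18.7 CPM in KO. The adaptor gene DOK3 reached 12.5 CPM and FAM222A 11.1 CPM. For PRR9, SPRR2D and IL13RA2 the 3 WT libraries held 2 counts each in all. Their ratios of counts, KO to WT, were 1699 (95% interval 470 to 14031), 911 (252 to 7526) and 892 (247 to 7371). SPRR2D belongs to a family of near-identical genes, so its reads are uncertain. As the naming rule required, all 10 passed the test, with adjusted p from 4.17e-16 to 6.55e-09 (edgeR). By the same rule they were higher in 3 of 3 KO libraries than in any WT library.

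The largest falls named were in genes well expressed in WT, as the minimum mean of 5 CPM requires of a gene that falls nearly to 0. ALDOC, an aldolase of glycolysis, fell from 641 ± 17.9 to 13.1 ± 0.904 CPM (SD, n = 3 each), a log2 fold change of -5.61 (SE 0.068). CA9, a carbonic anhydrase induced by hypoxia, fell from 157 ± 4.66 to 3.71 ± 0.292 CPM. ITGA10, a collagen-binding integrin, fell from 230 to 7.77 CPM, and KDELR3, a receptor that returns proteins to the endoplasmic reticulum, from 213 to 7.59 CPM. DEPP1 fell from 35.6 to 0.742 CPM, PTGS1, a cyclooxygenase, from 37.4 to 1.02 CPM, KRT15 from 43.6 to 1.20 CPM and SSC4D from 15.9 to 0.588 CPM. PCDHGC5 fell from 46.9 to 0.509 CPM and IFITM1 from 22.1 to 0.719 CPM, but PCDHGC5 shares exons with other protocadherin genes and IFITM1 has close paralogs, so both are uncertain. As the naming rule required, all 10 passed the test, with adjusted p from 2.97e-16 to 5.99e-12 (edgeR), and were lower in 3 of 3 KO libraries.

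Among the ferroptosis genes, the subunits of the cystine transporter rose and GPX4 fell. SLC7A11, which imports cystine, rose from 24.7 ± 1.75 to 172 ± 8.66 CPM (SD, n = 3 each), a 6.94-fold rise (log2 2.79, SE 0.067, adjusted p = 4.52e-14, edgeR). Its partner SLC3A2 rose from 286 ± 9.25 to 775 ± 67.9 CPM (log2 1.44, SE 0.065). GPX4, the selenoenzyme that reduces lipid peroxides, fell from 102 ± 5.24 to 33.4 ± 3.21 CPM (log2 -1.61, SE 0.074). ACSL4, which loads polyunsaturated fatty acids into lipids, fell from 241 ± 5.71 to 113 ± 9.88 CPM (log2 -1.10, SE 0.061). In each case all 3 KO libraries lay on the same side of all WT libraries.

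**Figure D1:**
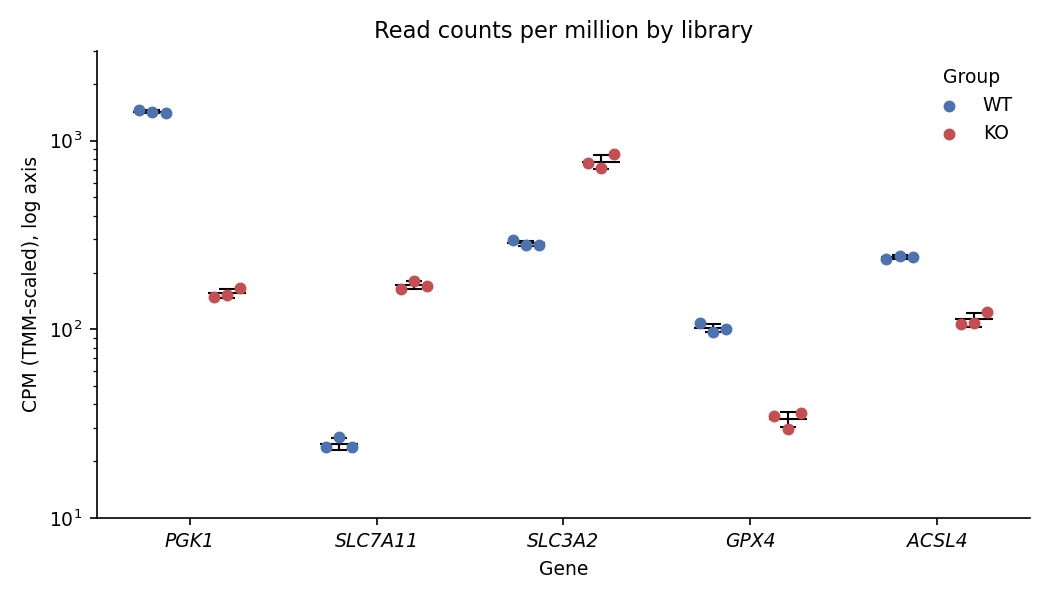
Scaled read counts (CPM, log axis) of PGK1 and the 4 ferroptosis genes named in advance. Points are the 3 libraries of each group, horizontal marks the means and error bars the SD. SLC7A11 lies near 24.7 CPM in WT and 172 CPM in KO, whereas GPX4 lies near 102 CPM in WT and 33.4 CPM in KO.

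The ferroptosis defence list held opposite movements. Of 23 measured members, 14 rose, 5 fell and 4 did not pass the test, with a median log2 fold change of 0.39. GCLM, a subunit of the enzyme that starts glutathione synthesis, rose from 34.3 to 126 CPM. MBOAT2 and SCD, which place monounsaturated fatty acids into lipids or make them, fell from 96.8 to 17.2 CPM and from 3743 to 741 CPM. As a list it was higher with camera (adjusted p = 0.0345), but adjusted p = 0.382 with an estimated correlation. Without WT library 1 or WT library 3 adjusted p was 0.0501 or 0.0565. With camera on log2 CPM after removal of the GC and length trend it was 0.255. With genes in more than 1 list left out the direction turned and adjusted p was 0.529. Of 24 measured members of the ferroptosis promotion list, 16 rose, 7 fell and 1 did not pass. The haem oxygenase gene HMOX1 rose from 21.6 to 159 CPM and CHAC1, a glutathione-degrading enzyme, from 18.3 to 59.7 CPM. SAT1 fell from 146 to 50.8 CPM and ELOVL5, a fatty acid elongase, from 364 to 116 CPM. This list was not called against other genes (camera adjusted p = 0.170), but was higher by fry, which tests against no change (adjusted p = 0.000593).

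Iron genes moved both ways. Of 16 measured, 7 rose, 8 fell and 1 did not pass, and with library size alone 8 were higher and 6 lower. FTH1, the ferritin heavy chain that stores iron, rose from 877 to 3151 CPM (log2 1.85). FBXL5, which directs the degradation of an iron regulatory protein, fell from 179 to 51.8 CPM and STEAP3, an endosomal iron reductase, from 281 to 156 CPM. The list was not called against other genes (camera adjusted p = 0.528; fry, higher, adjusted p = 0.0329), and its median (-0.12) and the direction of the test (higher) differed in sign.

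Targets of the stress factors NRF2 and ATF4 were mostly higher in KO. Of 28 NRF2 targets 17 rose, 7 fell and 4 did not pass, among them HMOX1, SLC7A11, GCLM and TXNRD1, a thioredoxin reductase that rose from 419 to 1123 CPM. The list was called with camera (adjusted p = 0.00543) but not with an estimated correlation (adjusted p = 0.203). The call was also lost with camera on log2 CPM after removal of the GC and length trend (adjusted p = 0.0628). With genes in more than 1 list left out the direction turned (adjusted p = 0.992). Of 32 genes of the ATF4 and amino acid response, 21 rose, 6 fell and 5 did not pass (median log2 0.52, camera adjusted p = 0.00062, adjusted p = 0.510 with an estimated correlation and 0.197 with genes in more than 1 list left out). PSAT1, of serine synthesis, rose from 146 to 513 CPM and WARS, the tryptophanyl-tRNA synthetase, from 141 to 471 CPM. DDIT4, an inhibitor of mTOR signalling that also responds to hypoxia, fell from 119 to 35.5 CPM. Among 15 genes of serine, glycine and folate metabolism, 5 rose, 5 fell and 5 did not pass (camera adjusted p = 0.852, fry adjusted p = 0.0279), with a median of 0.07 and a direction of lower in these tests. With library size alone 9 of them were higher and 3 lower. There ALDH1L1 fell from 118 to 18.9 CPM, SFXN1 from 136 to 60.0 CPM and GCAT from 18.1 to 4.03 CPM.

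Genes of the endoplasmic reticulum stress response were lower. Of 22 measured, 15 fell, 2 rose and 5 did not pass, and with library size alone 11 were lower and 6 higher (median log2 -0.40, camera adjusted p = 0.000936, adjusted p = 0.203 with an estimated correlation). The chaperone HSP90B1 fell from 2214 to 649 CPM, the disulfide isomerases PDIA4 and PDIA6 from 303 to 101 CPM and from 479 to 169 CPM, and CREB3L2, a membrane-bound transcription factor, from 251 to 59.1 CPM.

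Most glycolysis genes fell together with PGK1. Of 23 others measured, 18 fell, 3 rose (HK2, SLC16A1 and PFKFB3) and 2 did not pass (LDHB and BPGM, the last 5 named after their values were seen). Besides ALDOC, the enolase gene ENO2 fell from 370 ± 2.08 to 34.8 ± 1.41 CPM (SD, n = 3 each), SLC16A3, an exporter of lactate, from 401 to 118 CPM and PFKL, a phosphofructokinase, from 214 to 61.8 CPM. The median log2 fold change was -1.07 (camera adjusted p = 2.15e-11, adjusted p = 0.203 with an estimated correlation).

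**Figure D2:**
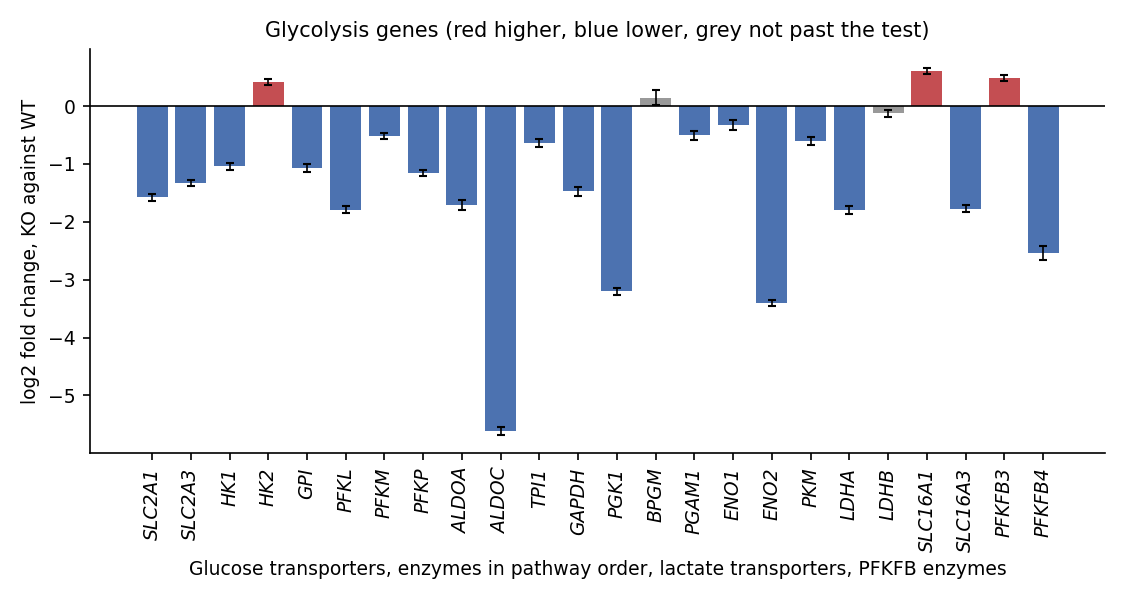
Log2 fold change (KO against WT) of glycolysis genes, with glucose transporters first, enzymes in pathway order, then lactate transporters and PFKFB enzymes. Bars show the edgeR estimates and error bars the SE. The changes range from -5.61 for ALDOC to 0.61 for SLC16A1, and 3 genes passed the edgeR test as higher.

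The hypoxia response was lower in KO. Of 21 measured targets of hypoxia-inducible factors, 18 fell, 2 rose and 1 did not pass, with a median log2 fold change of -1.80. CA9 fell as given above. P4HA1, a collagen prolyl hydroxylase, fell from 338 ± 10.8 to 31.2 ± 1.89 CPM (SD, n = 3 each), NDRG1 from 5203 to 597 CPM and BNIP3, a mitophagy receptor, from 232 to 34.3 CPM. The call (camera adjusted p = 1.94e-22) held with an estimated correlation (adjusted p = 0.0345).

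Lists for other routes of carbon metabolism were not called against other genes by camera, though fry, which tests against no change, called 2 of the 3 lower. In the pentose phosphate pathway 3 of 10 genes rose, 4 fell and 3 did not pass (camera adjusted p = 0.198, fry adjusted p = 0.00116): the transketolase TKT fell from 1362 to 559 CPM, PRPS2 from 155 to 42.0 CPM and RBKS from 2.17 to 0.267 CPM. In the TCA cycle and pyruvate entry 11 of 29 rose, 15 fell and 3 did not pass (camera adjusted p = 0.107, fry adjusted p = 0.000593). SUCLG2, a succinyl-CoA ligase subunit, fell from 242 to 28.5 CPM, IDH2 from 23.5 to 3.76 CPM, PDK1, which inhibits pyruvate dehydrogenase, from 71.4 to 19.4 CPM, and the pyruvate carboxylase gene PC from 41.1 to 6.32 CPM. Without the filter on low counts this list was called lower (adjusted p = 0.0373). Of 52 nuclear genes of oxidative phosphorylation 22 rose, 14 fell and 16 did not pass (camera adjusted p = 0.593, fry adjusted p = 0.389), and with library size alone 30 were higher and 9 lower. CYCS, cytochrome c, rose from 125 to 294 CPM and ATP5MC3 from 58.2 to 99.2 CPM, while NDUFV1 fell from 114 to 57.0 CPM and UQCRC1 from 270 to 150 CPM.

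Cholesterol synthesis genes fell almost throughout. Of 25 measured, 23 fell, 1 rose and 1 did not pass, with a median log2 fold change of -2.30. MSMO1, a sterol demethylase, fell from 707 ± 30.7 to 60.6 ± 3.21 CPM (SD, n = 3 each). INSIG1, a sterol sensor partner, fell from 432 to 47.1 CPM, the mevalonate enzymes MVD from 150 to 14.3 CPM and FDPS from 274 to 38.8 CPM. The call (camera adjusted p = 7.49e-35) held with an estimated correlation (adjusted p = 0.0248). Of 20 genes of fatty acid synthesis and desaturation, 11 fell, 6 rose and 3 did not pass (median log2 -0.72, camera adjusted p = 0.00971, adjusted p = 0.203 with an estimated correlation). FASN fell from 2735 to 923 CPM and FADS1, a desaturase, from 208 to 104 CPM. This call was lost with camera on log2 CPM after removal of the GC and length trend (adjusted p = 0.0721). It was also lost with genes in more than 1 list left out (adjusted p = 0.351).

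Mitotic genes fell while DNA replication genes moved both ways. All 24 measured G2/M genes fell, with a median log2 fold change of -2.10 (camera adjusted p = 1.12e-17, adjusted p = 0.0583 with an estimated correlation). TOP2A, a topoisomerase, fell from 272 ± 8.48 to 43.0 ± 3.00 CPM (SD, n = 3 each), the mitotic kinase PLK1 from 72.2 to 9.41 CPM, HMMR from 30.2 to 2.77 CPM and the kinesin KIF20A from 41.4 to 4.56 CPM. Of 24 G1/S and replication genes, 12 rose, 8 fell and 4 did not pass (camera adjusted p = 0.962). MCM3, a helicase subunit, rose from 42.9 to 95.6 CPM, while CCND1 fell from 2442 to 1038 CPM, CDT1 from 70.3 to 26.6 CPM and RRM1 from 97.5 to 53.5 CPM. The difference of the medians, G2/M minus G1/S, was -2.23 (2-sided permutation test across genes, p = 1e-05, the smallest value the resamples can give), although genes are not independent replicates. This comparison was not among the tests fixed in advance. Many other pairs of lists could have been compared, so its p-value is descriptive only. AURKA, TPX2, UBE2C and PCNA lie on chromosome 20 and were not measured.

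Targets of p53 and genes of ribosome assembly rose. Of 25 p53 targets, 18 rose, 4 fell and 3 did not pass (median log2 0.56, camera adjusted p = 0.000936, adjusted p = 0.0675 with an estimated correlation). MDM2, which restrains p53, rose from 120 to 486 CPM, XPC from 44.7 to 120 CPM and TIGAR, a fructose bisphosphatase, from 24.9 to 73.2 CPM, whereas CCNG1 fell from 510 to 183 CPM. Of 23 MYC and ribosome biogenesis genes, 16 rose, 2 fell and 5 did not pass (median log2 0.74, camera adjusted p = 4.69e-06, adjusted p = 0.0811 with an estimated correlation). POLR1A, of RNA polymerase I, rose from 51.1 to 153 CPM, ODC1, of polyamine synthesis, from 230 to 721 CPM, NOP58 from 55.0 to 187 CPM and WDR43 from 96.5 to 245 CPM. Among replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 8 of 12 rose, 1 fell and 3 did not pass. HIST1H2AC rose from 17.1 to 56.4 CPM and HIST1H2BK from 42.3 to 94.8 CPM, while HIST1H4H and HIST1H4C rose from near 0 to 7.88 and 0.957 CPM. This list was barely called (camera adjusted p = 0.0457, adjusted p = 0.408 with an estimated correlation). The call was lost without WT library 1 (0.0501), WT library 2 (0.0661), KO library 2 (0.0567) or KO library 3 (0.0596), and with upper-quartile scaling (0.0526) or library size alone (0.0823). It was also lost without a filter (0.0796), with at least 1 CPM in 3 libraries (0.0615) and with genes in more than 1 list left out (0.0645).

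Most extracellular matrix genes fell. Of 25 measured collagen and extracellular matrix genes, 21 fell, 3 rose and 1 did not pass, with a median log2 fold change of -1.63. THBS1 fell from 898 ± 8.31 to 73.2 ± 4.86 CPM (SD, n = 3 each), LOXL2, which crosslinks collagen, from 797 to 64.8 CPM, SPARC from 1138 to 108 CPM and COL4A2 from 943 to 168 CPM. The call (camera adjusted p = 5.15e-22) held with an estimated correlation (adjusted p = 0.0345). Of 18 TGF-beta and YAP targets, 13 fell, 3 rose and 2 did not pass (median log2 -0.55, camera adjusted p = 7.75e-05, adjusted p = 0.0583 with an estimated correlation). CTGF fell from 3485 to 251 CPM, CYR61 from 2221 to 834 CPM and F3, tissue factor, from 235 to 57.4 CPM. Among 16 matrix proteases and invasion genes 10 fell, 4 rose and 2 did not pass (camera adjusted p = 0.0565; fry, lower, adjusted p = 6.86e-06). The membrane protease MMP14 fell from 5952 to 757 CPM, the urokinase PLAU from 379 to 43.4 CPM and the integrin ITGB3 from 41.7 to 2.62 CPM, in contrast to MMP3 and MMP1. The median of this list was -0.80 and its mean 0.07. It was called lower with library size alone (adjusted p = 0.0146) and with a filter of at least 1 CPM in 3 libraries (adjusted p = 0.0367).

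Lists of inflammatory, interferon and lysosomal genes were not called against other genes by camera, while fry called the first 2 lower and the third higher. Of 19 NF-kB and cytokine genes 7 rose, 7 fell and 5 did not pass (camera adjusted p = 0.959, fry adjusted p = 0.0110), with a median of 0.19 and a direction of lower in these tests. CXCL8, interleukin 8, rose from 1.33 to 16.8 CPM, whereas NFKB2 fell from 168 to 67.4 CPM, RELB from 37.5 to 16.7 CPM and IL1B from 43.4 to 31.8 CPM. Of 22 interferon-response genes 11 fell, 4 rose and 7 did not pass (camera adjusted p = 0.675, fry adjusted p = 0.00200). DDX58, an RNA sensor, fell from 27.8 to 10.9 CPM, while IFIT3 rose by 1.64 and IRF1 by 1.02 on the log2 scale. Of 25 autophagy and lysosome genes 12 rose, 6 fell and 7 did not pass (camera adjusted p = 0.181, fry adjusted p = 0.00520). MAP1LC3B rose from 106 to 380 CPM, ATP6V0D1, a proton pump subunit, from 27.9 to 113 CPM and SQSTM1, an autophagy receptor and NRF2 target, from 585 to 1671 CPM, while WIPI1 fell from 72.7 to 18.2 CPM.

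**Figure D3:**
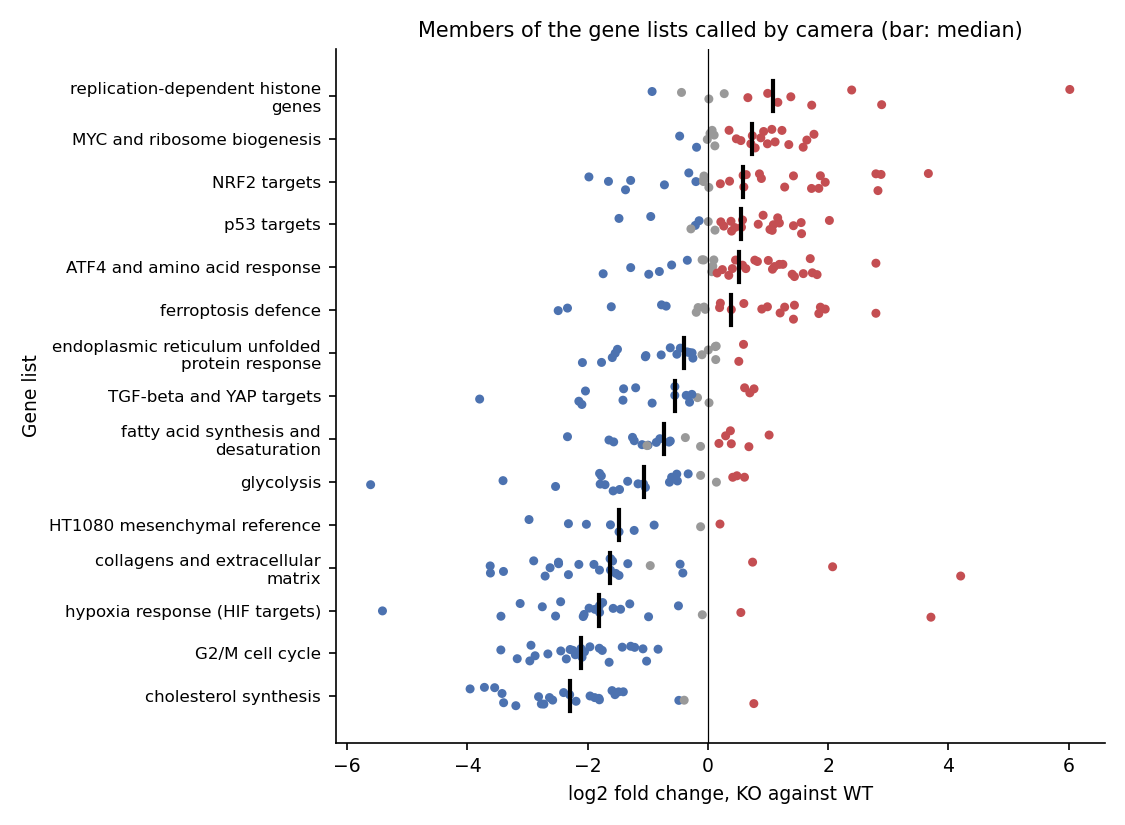
Log2 fold change (KO against WT) of the members of the 15 gene lists called by camera. Each point is a gene, red where higher, blue where lower and grey where the test was not passed, and the black bar is the median of the list. Medians range from -2.30 for cholesterol synthesis to 1.08 for histone genes.

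Markers of the mesenchymal state of HT1080 fell. Of 9 measured, 7 fell, 1 rose and 1 did not pass (median log2 -1.48, camera adjusted p = 4.69e-07, adjusted p = 0.0653 with an estimated correlation and 0.134 with genes in more than 1 list left out). VIM, vimentin, fell from 7873 ± 196 to 1939 ± 221 CPM (SD, n = 3 each), FN1, fibronectin, from 3418 to 685 CPM and COL6A2 from 174 to 62.5 CPM. Markers of other cell types were not called as lists against other genes by camera, while fry called the haematopoietic markers higher and the endothelial markers lower. Of 5 measured epithelial markers 2 rose, 2 fell and 1 did not pass (camera adjusted p = 0.852, fry adjusted p = 0.311): ESRP1 and CDH1 rose to 2.63 and 0.964 CPM, and KRT8 fell from 179 to 78.1 CPM. Of 5 haematopoietic markers 3 rose and 2 fell (camera adjusted p = 0.672, fry adjusted p = 0.0103), with SPI1 at 1.61 CPM and CD53 at 2.27 CPM in KO, and LCP1, abundant in both groups, at 866 and 1002 CPM. Of 5 endothelial markers 3 fell, 1 rose and 1 did not pass (camera adjusted p = 0.479, fry adjusted p = 0.000104), with PECAM1 falling by 2.38 on the log2 scale and TIE1 by 0.59.

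In all, 15 of 29 lists were called by camera at an adjusted p under 0.05, 6 higher and 9 lower in KO, and 3 of these calls held with an estimated correlation, those of cholesterol synthesis, hypoxia and extracellular matrix. Counts of members are over all genes tested. Adjusted over the list alone they differed in 5 lists: 17 TCA genes fell, 3 endoplasmic reticulum genes rose, 10 interferon genes fell, 6 NF-kB genes rose and 22 matrix genes fell. In the other 24 lists they were equal. With library size alone the counts higher and lower became 6 and 3 for the pentose phosphate pathway, 12 and 12 for the TCA cycle, 16 and 3 for autophagy, 5 and 6 for interferon and 7 and 4 for NF-kB. The medians of 4 uncalled lists turned positive with library size alone, to 0.18 for the pentose phosphate pathway, 0.07 for the TCA cycle, 0.10 for iron and 0.17 for epithelial markers, and the first was also positive with upper-quartile scaling (0.01).

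Genes of chromosome 20 were near 0 in every library. A mean of at least 100 counts was reached in both groups by 0.95% of its 525 protein-coding genes, against 42.9 to 59.9% on the other autosomes and X. Of the 16 list members there, 11 had no count in any library, and the highest sum over the 6 libraries was 32, for MMP9. Of 47 genes of this chromosome that passed the filter, 24 were called, and without them 10091 genes changed.

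**Figure D4:**
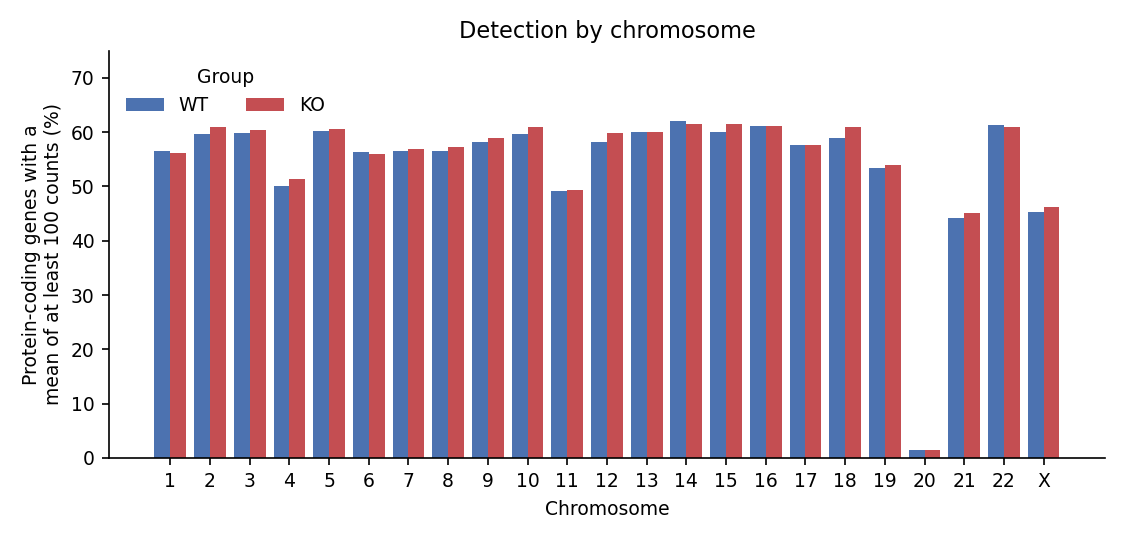
Share of protein-coding genes with a mean of at least 100 counts (percent), by chromosome, in WT and KO. Chromosome 20 stands at 1.52% in WT, and the other chromosomes at 44.2% or more in WT.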

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

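The alternatives without the chromosome 20 genes and with the GC and length trend removed were chosen after seeing the data. The count of changed genes was 9384 to 10759 under the other scalings, filters and tools, against 10116, and ranged from 9687 to 10676 with each library left out. It moved with the threshold: 4104 (2048 higher, 2056 lower) with an absolute log2 fold change of at least 1, and 5392 (2749 higher, 2643 lower) with edgeR's test against a 1.5-fold change, since both ask for more than a difference from 0. The FPKM fits called 10296 to 10759 genes, 63.1 to 64.1% of them higher, as they use library size alone. PGK1 kept its call throughout, with log2 fold changes from -3.39 to -2.96. With each library left out 13 to 15 lists were called. With an estimated correlation camera called 3 lists (0 higher, 3 lower), since it allows for correlated members. The fry test, which compares no list with other genes, called 26 (10 higher, 16 lower). With genes in more than 1 list left out 9 lists were called (2 higher), the ferroptosis defence list turned lower (adjusted p = 0.529) and so did the NRF2 list (adjusted p = 0.992). No pairing by replicate number was seen: deviations of same-numbered libraries from their group means correlated at -0.04, -0.02 and -0.05. With 3 libraries per group these values cannot exclude that same-numbered libraries were handled together. A replicate block gave 9986 changed genes and changed no list call. For named genes, 2523 results kept their direction and side of the threshold, 11 lost their call and 0 reversed. The lost calls were those of CLDN4, TEK, PRPS1 and LCP1. At this depth a log2 change of 0.32 was recovered in 38% of simulated cases, so uncalled genes can hold changes of that size. The simulation gave every gene the same dispersion, changed no low-count genes and changed few genes in all. Recovery for low-count or more variable genes, or where most genes change, is therefore not known.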

Other observations

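The families and tests in this part were chosen after the data were seen. The 12 gene families were picked by symbol, some of them because members had been seen to change. Families with genes already named above or held in a list were therefore tested again without those genes. The zinc-finger, cytosolic and mitochondrial ribosomal protein, proteasome, TCP1 chaperonin and initiation factor 3 families held no such genes. For them the second test used the same genes and gives no check on that choice. The collagen-modifying enzymes and the genes matched by symbol as integrins were lower in KO. Of 9 prolyl and lysyl hydroxylases 8 fell and 0 rose, with a median log2 fold change of -1.80 (camera adjusted p = 2.7e-11, adjusted p = 0.0422 with an estimated correlation). Without P4HA1, P4HA2 and PLOD2, 5 of 6 fell (camera adjusted p = 7.92e-05, adjusted p = 0.236 with an estimated correlation). P3H3 fell by 2.50 on the log2 scale and PLOD1, a lysyl hydroxylase, by 1.61. Of 25 genes matched as integrins 15 fell and 4 rose (median -1.12, camera adjusted p = 2.14e-05, adjusted p = 0.0428 with an estimated correlation), with ITGA6 at -1.96 and ITGB1 at -1.12. The match used only the start of the symbol. It therefore also took in ITGBL1 (-2.09), an integrin-like gene that is not an integrin subunit, and may hold other such genes. The integrin values given here are thus not of integrin subunits alone. Without ITGA10, ITGB3 and 3 others named above or in a list, 11 of 20 fell (camera adjusted p = 0.0170, adjusted p = 0.236 with an estimated correlation). Kinesins fell in 16 of 30 cases (camera adjusted p = 0.0173, adjusted p = 0.371 with an estimated correlation), and were not called without those in the lists (adjusted p = 0.0844).

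Other families were higher with the preset correlation alone. Of 425 zinc-finger genes named ZNF 277 rose and 40 fell, with a median log2 fold change of 0.69 (camera adjusted p = 4.8e-06, adjusted p = 0.394 with an estimated correlation). ZNF416 rose by 2.98 and ZNF622 by 1.76 on that scale. Mitochondrial ribosomal proteins rose in 52 of 76 cases (camera adjusted p = 0.0139, adjusted p = 0.690 with an estimated correlation), led by MRPL1 at 2.21. Proteasome subunits rose in 25 of 36 cases (camera adjusted p = 0.0411, adjusted p = 0.690 with an estimated correlation), while PSMB9, of the immunoproteasome, fell by 2.24. All 5 measured small proline-rich and late cornified envelope genes rose (camera adjusted p = 0.0455, adjusted p = 0.399 with an estimated correlation), and without SPRR2D they were not called (adjusted p = 0.288). The medians of these 7 families kept their sign under all 3 other scalings. Cytosolic ribosomal proteins, TCP1 chaperonin subunits, initiation factor 3 subunits, protocadherins and heat shock genes were not called (camera adjusted p = 0.744, 0.138, 0.850, 0.849 and 0.0621). Close to PGK1 on chromosome X, ATRX and ATP7A rose by 0.84 and 1.10, MAGT1, TAF9B and RTL3 fell by 0.63, 0.71 and 0.65, and COX7B (-0.14, adjusted p = 0.160) and PGAM4 (-0.17, adjusted p = 0.723) did not pass the test (edgeR).

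The near-absence of chromosome 20 genes was weighed between a loss in the processing and a loss in the cells. In WT 1.52% of its protein-coding genes reached a mean of 100 counts, so a loss of the chromosome in the knockout cells cannot explain the gap. The share was 0.95% in both groups together, and 11 of the 16 list members there had no count in any library, PCNA, which DNA replication requires, among them. These values are consistent with reads of this chromosome left uncounted in the authors' processing, at a step that the sources used here do not name. No other autosome, nor X, showed a loss of this size (at least 42.9% of genes at that level in both groups), and effects on single genes elsewhere were not tested.

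The PGK1 transcript left in KO, 10.8% of WT by summed counts, was weighed against a share of unedited cells and against reads of PGK2. Unedited cells that kept their WT levels in the KO culture would bring all WT transcripts at that share. Yet 11 genes with a WT mean of at least 30 CPM had an upper 95% limit under 0.5 of it, and ALDOC stood at 2.05% by scaled means. These values speak only against such cells as the source of all of the remaining PGK1 transcript. A smaller share of unedited cells stays possible. The lowest, PCDHGC5 at 1.03%, shares exons with other genes and is uncertain. PGK2 had 0 counts in the KO libraries, which argues against reads of that paralog. Edited transcripts that escape decay may account for the remainder, as may reads from processed copies of PGK1, and neither was tested here. Of 23 other glycolysis genes 18 also fell and 3 rose (median log2 fold change -1.07), with ENO2 at 9.41% of WT. How much of the fall of PGK1 came from the editing was therefore not separated from the fall of its pathway.

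Low-expressed genes were higher in KO: among 2487 genes with a mean of 0.1 to 1 CPM the median log2 ratio of KO to WT was 0.60, against -0.11 among 2361 genes of at least 100 CPM. An even background of reads would give 78.9 to 89.4% of 399 olfactory receptor genes a read in the KO libraries, but on average 10.03% had a read, against 4.51 to 6.77% in the WT libraries. Deeper knockout libraries are not the reason, since 2 KO libraries had a smaller total than every WT library and still a higher median FPKM of these genes. The 1470 of these genes that passed the filter and have a known GC content lay 0.548 (bootstrap SE 0.073) above genes of at least 10 CPM before removal of the trend on GC content and length, and 0.587 (SE 0.057) after it. An effect of the knockout and a difference between the clones or cultures, which the labels do not describe, stay open and untested.

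With 10 ways to split the 6 libraries into groups of 3, no share under 0.05 can be had. The real split gave 10116 genes and the highest other split gave 0 genes, and 1 of 10 splits, the real one itself, gave as many genes. Every other split mixes WT and KO libraries within its groups, so their difference adds to the spread there. The 0 genes in those splits therefore do not measure the rate of false calls. For the gene lists the real split gave 15, the highest other split 10 and the lowest other split 7. Again 1 of 10 splits, the real one itself, gave as many lists. Lists were thus called in splits where no gene passed the test. Each of those splits holds unequal numbers of WT and KO libraries on its sides, so part of their difference stays in the comparison. The list calls there therefore do not measure the rate of false calls of the list test either.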
